A study of Arabidopsis thaliana with 6 samples.

How the data were processed

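Gene expression was measured in whole Arabidopsis thaliana seedlings grown for 4 days in darkness, on 6 Affymetrix ATH1 arrays, a 1-colour design in which biotin-labelled RNA of 1 sample is hybridised to each array. Per the labels' protocols, seeds were kept in the cold for 4 days, given 1 hour of light to induce germination and then kept at 21 °C in the dark. Total RNA was isolated and column-purified, and labelled RNA was prepared from 20 µg of it, per the labels. The groups were wild type (Col-0) and pif1-2, an insertion mutant of PIF1, with 3 arrays each. Group and replicate number were taken from the sample titles, because the allele number in another label field counts upwards from sample to sample.

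The deposited values are MAS5 signals, a linear intensity per probe set, per the submitters' processing notes, which name MAS5; its version and settings are not given in the sources used here. The authors had scaled each array, as the values show: the 2% trimmed mean of the deposited intensity lay at 500 on every array. MAS5 summarises each probe set within its own array, so weak signals are noisy and fold changes of dim probe sets are imprecise. The deposited table held 22810 probe sets, of which 64 Affymetrix controls were used only to describe the arrays.

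From there, each array was rescaled to a 2% trimmed mean of 500 over the remaining probe sets, 5051 probe sets with a mean scaled signal under 50 over all 6 arrays were left out, and log2(signal + 16) was taken of the other 17695. Fold changes are on that scale, which understates the change of dim probe sets. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), as pif1-2 minus wild type, two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Gene lists were compared with the other probe sets by camera of limma, with its preset correlation between genes of 0.01, two-sided, and adjusted over the lists. Levels are given as mean ± SD of the scaled signal, n = 3 arrays per group. The number of arrays limits the precision.

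Probe sets were named from the platform annotation supplied for these probes. It gave 1 gene for 13513 probe sets and several for 503, and 8730 were not listed in it and stay unnamed here. Of the probe sets tested, 9981 (56.4%) had 1 gene, and 13436 of the named probe sets matched the RefSeq gene table of assembly TAIR10.1, which was used for names only. No genome build is given in the sources used here and no coordinates are printed. A gene with several probe sets was represented in the lists by the brightest. Of the 355 genes on the 20 lists fixed beforehand, 56 had a named probe set. The lists, the fit, the alternatives and the rule for named genes were chosen before the data were examined. In addition, 18 groups were defined by patterns in the gene symbols after the annotation had been seen and before any test was run, and members and values of 2 of them are not reported here.

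The rule named PIF1 and AT2G20810 first. It then took the probe sets with 1 gene that passed the threshold with an absolute log2 fold change of at least 1 and no overlap between groups and, since fewer than 6 passed, the 10 with the smallest p. From each fixed list it took the members past the threshold, filled up with those of smallest p to 2 (4 for the chlorophyll, heme and photosystem lists). The same was done for the 18 added groups. Any other gene named was chosen after its values were seen: the called probe set without a gene name, further members of the lists described in full, and the genes of amino acid breakdown.

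The fit was tested on simulated data with the spread of the real probe sets: over 20 runs of the pif1-2 and wild-type comparison with 17695 probe sets, 200 of them changed, it called 69.6% of 2-fold and 92.9% of 4-fold changes, and 5.91% of its calls were false. The simulated noise was normal and independent between probe sets, with no outlying array. These shares are therefore not the power for the real arrays. A list of 40 independent simulated genes shifted by -0.30 was called, at an unadjusted camera p under 0.05, in 20 of 20 runs, and an unshifted list in 0 of 20. The fixed lists were smaller, were adjusted, and hold genes that may vary together. Those runs therefore do not give the power or false calls for them.

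Alternatives covered the pseudocount, a floor, the scaling, the filter, the variance model, array weights, the replicate number as a block, leaving out each array, and for the lists an estimated correlation in camera and the rotation test fry. The labels call the replicates biological and do not say whether seedlings were grown as separate batches, so the p-values measure the spread between these samples. Array quality was described by the 3-prime to 5-prime signal ratios of control genes and compared by exact permutation tests, for which 3 arrays against 3 cannot give a p below 0.1.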

Results

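Transcript levels were compared between dark-grown wild-type (Col-0) and pif1-2 seedlings of Arabidopsis thaliana, with 3 ATH1 arrays per group. PIF1 is a basic helix-loop-helix transcription factor that binds phytochrome and is known to restrain seed germination and chlorophyll synthesis in darkness. Per the labels, PIF1 mRNA is very low in pif1-2, and etiolated wild-type seedlings stand about 2 mm taller than the mutant. The comparison asks which transcripts depend on PIF1 in seedlings that have seen almost no light. The median deposited signal was between 184 and 199 on the 6 arrays, and 21.7% to 23.7% of the probe sets lay under the low-signal limit of 50. Pearson correlations of log2 signals, taken across probe sets, ranged from 0.954 to 0.970 between arrays of a group and from 0.955 to 0.974 between arrays of different groups. The array of pif1-2 replicate 3 stood apart from the other 5 on the first principal component, which held 26.9% of the variance, with a score of 47.9 against -13.2 to -5.23. Its actin 3-prime to 5-prime ratio was 8.07, against 3.53 to 5.17 on the others, and 1.74 against 1.28 to 1.63 on a second set of actin control probe sets. On the second component (23.5% of the variance) the replicate 1 arrays lay together, at -22.4 for wild type and -27.4 for pif1-2, against 0.875 to 30.9. Their correlation of 0.974 was the highest of all pairs. The array of pif1-2 replicate 2 stood apart on the third component (22.5% of the variance), at -42.6 against 1.97 to 17.8, and its deposited 25S rRNA signal was 545.5, against 5876.6 to 13935.5 on the others. Exact two-sided permutation tests of the ratios between the groups, which cannot go below 0.1 with 3 arrays against 3, gave p = 0.3 for actin, 0.4 for GAPDH and 0.8 for ubiquitin, and 0.6, 0.2 and 0.6 on the second set.

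The mutated gene itself was not analysed here by name. The series title prints locus At2g20810 beside the allele, whereas the gene table used here lists PIF1 at AT2G20180, and 0 named probe sets belonged to either locus. The genotype of the arrays therefore rests on the labels, with no target-gene check by name. PIF1 may be measured by one of the 8730 probe sets that the annotation did not list. Whether 265584_at, the unnamed probe set called below, measures the mutated gene itself or another gene is not known here.

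In pif1-2 seedlings 2 of 17695 probe sets passed the threshold, and both were lower than in wild type. The larger fall was that of probe set 265584_at, whose gene is not named in the annotation used here: its signal was 350 ± 41.5 (SD, n = 3) in wild type and 13.9 ± 9.53 in pif1-2, a log2 fold change of -3.66 (SE 0.32, limma adjusted p = 0.00161). The other was AT5G57760, a locus without a gene symbol in the annotation, which went from 1111 ± 97.1 to 441 ± 81.5 (log2 fold change -1.31, SE 0.17, limma adjusted p = 0.0414). For both, all 3 pif1-2 arrays lay below all 3 wild-type arrays. None was called higher by limma, although 585 probe sets were higher and 772 lower at an unadjusted p under 0.05, 1357 in all where independent probe sets would give about 885 by chance. With median centring 685 were higher and 669 lower, so the tilt towards lower depends on the scaling, and other splits of the 6 arrays into 3 and 3 gave up to 1666 probe sets. Of the 128 that also differed at least 2-fold, 91 were lower and 37 higher in pif1-2. The groups did not overlap for 13.1% of the probe sets, against 10% by chance. With the replicate number as a block 45 passed, 11 higher and 34 lower. The number of calls rested on single arrays: it was 7 without wild type replicate 1, 0 without wild type replicate 2 and 1 without any 1 of the other 4, and the unadjusted count was 815 without wild type replicate 2 and 904 without wild type replicate 3. 265584_at missed the threshold only without wild type replicate 2 (adjusted p = 0.0615) among all settings tried, and AT5G57760 missed it when any 1 array was left out (0.0534 to 0.234). As the pif1-2 signal of 265584_at is close to 0, its fold depends on the pseudocount, from -2.41 with 64 to -4.78 with 1.

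**Figure D1:**
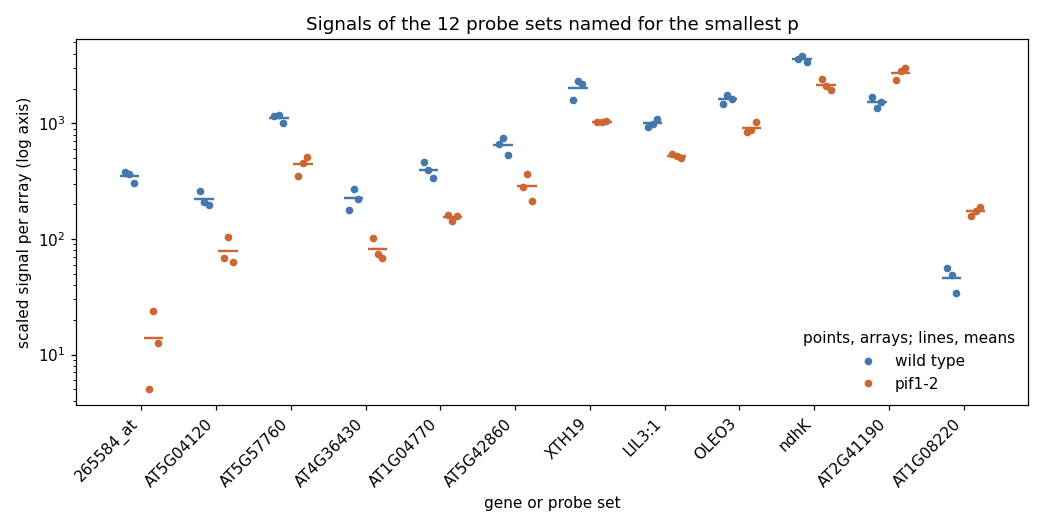
Scaled signal on each array (vertical log axis) for the 12 probe sets named for the smallest p, ordered by log2 fold change, with points for arrays and lines for means of 3 wild-type and 3 pif1-2 arrays. The pif1-2 arrays lie apart from the wild-type arrays in each, which the choice by smallest p favours. For 265584_at the means are 350 in wild type and 13.9 in pif1-2.

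The next 10 genes by p did not pass the threshold, with limma adjusted p-values from 0.0607 to 0.152. Most were lower in pif1-2. LIL3:1, a light-harvesting-like protein that anchors geranylgeranyl reductase in the thylakoid, had a signal of 1003 ± 72.8 in wild type and 522 ± 20.8 in pif1-2 (log2 fold change -0.92, SE 0.14, adjusted p = 0.112). XTH19, a xyloglucan endotransglucosylase/hydrolase that remodels the cell wall, stood at 2038 ± 387 and 1032 ± 8.67 (-0.95, SE 0.16). It passed without wild type replicate 1 (adjusted p = 0.0226). OLEO3, an oleosin of the oil-body coat, was measured at 1624 ± 141 and 919.7 ± 103 (-0.81, SE 0.14), and ndhK, a plastid-encoded subunit of the NDH complex, at 3619 ± 222 and 2156 ± 247 (-0.75, SE 0.13). The loci AT5G04120, AT4G36430, AT1G04770 and AT5G42860 had log2 fold changes of -1.35, -1.29, -1.28 and -1.16. Of the 10, AT1G08220 and AT2G41190 were higher in pif1-2, the first from 46.2 ± 11.4 to 175 ± 15.5 (log2 fold change 1.63, SE 0.28) and the second from 1526 ± 169 to 2734 ± 336 (0.83, SE 0.15). In each of the 10 the pif1-2 and wild-type arrays did not overlap, which the choice by smallest p favours. With array weights AT1G04770, LIL3:1, XTH19 and OLEO3 passed, and with the replicate number as a block 9 of the 10 passed, all but AT4G36430 (adjusted p from 0.00887 to 0.0459).

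Cell wall expansion genes of a fixed list, of which expansins and xyloglucan endotransglucosylases were tested (8 of 26 genes), were lower in pif1-2 as a set. The median log2 fold change of the 8 members tested was -0.32, and 7 of the 8 were negative (camera p = 0.0052, adjusted p = 0.0497 over 14 lists; adjusted p = 0.565 with an estimated correlation). Over all genes 0 members passed with limma, with 3 lower and 1 higher at an unadjusted p under 0.05. Adjusted over the list alone, XTH19 and EXPA9 were lower. EXPA9, an expansin, which loosens cell walls, had signals of 1981 ± 741 and 963 ± 319 (log2 fold change -1.01, SE 0.27, limma adjusted p = 0.410 over all genes). EXPA8 ran the other way, at 5749 ± 456 and 7240 ± 557 (0.33, SE 0.13). Every pif1-2 array had a lower list median than every wild-type array. A wider group of 34 expansin, XTH and GH9 genes, which holds these 8, had a median of -0.014 (0.0070 with median centring, -0.17 to -0.026 without 1 array) and a mean of -0.11 (camera adjusted p = 0.373 over the 18 added groups). The call was lost without wild type replicate 2 (median -0.18, adjusted p = 0.138), pif1-2 replicate 1 (-0.21, 0.223) or pif1-2 replicate 3 (-0.32, 0.143), with median centring (0.0579), with no filter (0.0819), with a filter at 100 (0.0540), with the replicate number as a block (0.0553) and with fry (0.218).

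The tested genes of the chlorophyll branch and the common tetrapyrrole steps, 11 of the 30 fixed, were also lower as a set. Only 12 of the 30 had a named probe set, and the others may be measured by probe sets that carry no single gene name here. The 11 members tested had a median log2 fold change of -0.23, with 9 negative (camera p = 0.0071, adjusted p = 0.0497; adjusted p = 0.619 with an estimated correlation). With limma 0 members passed over all genes and 0 adjusted over the list alone, and 2 were lower and 0 higher at an unadjusted p under 0.05. PORB, a protochlorophyllide oxidoreductase, had signals of 9261 ± 1268 in wild type and 6800 ± 2175 in pif1-2 (log2 fold change -0.48, SE 0.20, and -0.27 without pif1-2 replicate 3). AT1G74470, the geranylgeranyl reductase that makes the phytol chain of chlorophyll, had 12074 ± 89.0 and 9580 ± 699 (-0.34, SE 0.12). The log2 fold changes of HEME2, a uroporphyrinogen decarboxylase, and GSA1, a glutamate-1-semialdehyde aminotransferase, were -0.27 (SE 0.14) and -0.21 (SE 0.14), GSA1 at -0.13 without wild type replicate 2. CHLM, a magnesium-protoporphyrin methyltransferase, was at 0.13 (SE 0.13). The list median on the array of pif1-2 replicate 2, relative to the wild-type mean, was -0.0055 and lay among the wild-type arrays, while the other pif1-2 arrays were at -0.31 and -0.36. The call was lost when any array other than pif1-2 replicate 2 was left out (adjusted p = 0.0697 to 0.306), with a pseudocount of 64 (0.0534), with median centring (0.0579), with no filter (0.109), with a filter at 100 (0.0878), with the replicate number as a block (0.0690) and with fry (0.382).

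**Figure D2:**
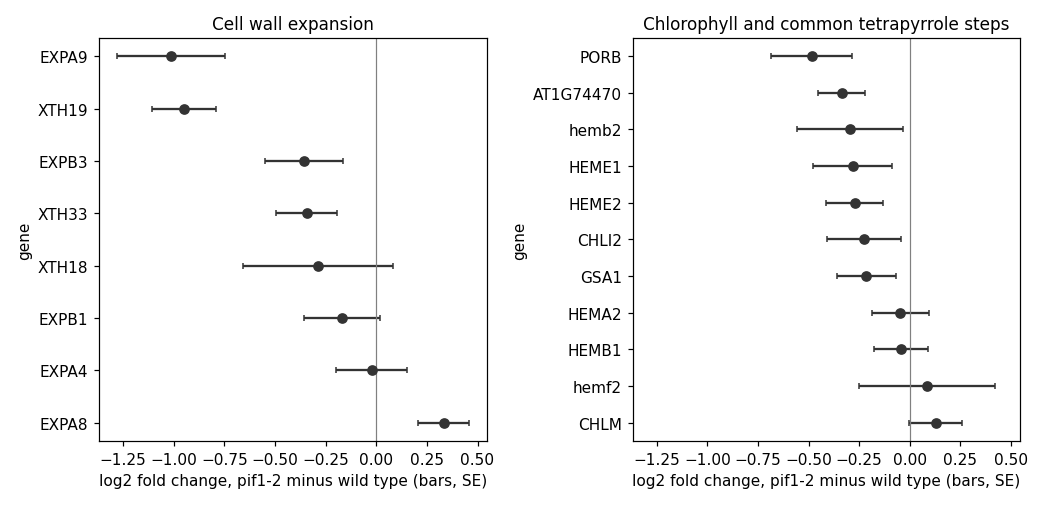
Log2 fold change of pif1-2 minus wild type for the members of the cell wall expansion list and of the chlorophyll and tetrapyrrole list, 1 row per gene, with bars for the SE of the limma fit (3 arrays per group). Of the 8 wall genes 7 are negative, EXPA9 lowest at -1.01, and of the 11 tetrapyrrole genes 9 are negative, PORB lowest at -0.48.

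None of the fixed lists of nuclear photosynthesis genes passed the threshold, and few of their members were tested. The 7 light-harvesting and photosystem genes tested had a median log2 fold change of 0.030 (-0.012 with quantile normalization; camera adjusted p = 0.476), with PSAN, a photosystem I subunit, at 0.36 (SE 0.16), LHCB4.1 and LHCB4.2 both at 0.12 and LHCB4.3 at -0.035. The carbon fixation and electron carrier list had 3 genes tested, RCA at -0.26 (-0.44 to -0.14 without 1 array), SBPASE at -0.19 (-0.33 to -0.050) and PRK at -0.097 (adjusted p = 0.476), and a list median from -0.33 to -0.10 without 1 array. The carotenoid and plastid isoprenoid list was measured by LYC, a lycopene cyclase, at -0.15 and Z-ISO, a carotene isomerase, at -0.18. None of these 12 genes passed over all genes or adjusted over its list alone with limma, and 1 of them, PSAN, had an unadjusted p under 0.05 (0.0415).

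Plastid-encoded transcripts for photosynthetic complexes and the NDH complex, a group defined from the gene symbols, were lower in pif1-2. The 43 probe sets tested had a median log2 fold change of -0.23 and 35 were negative (camera p = 3.3e-09, adjusted p = 6.0e-08 over the 18 added groups; adjusted p = 0.901 with an estimated correlation, and 0.381 with fry). With limma 0 passed over all genes, 14 were lower and 0 higher at an unadjusted p under 0.05, and 6 were lower when adjusted over the group alone: ndhK, petG, ndhG, psbD, ndhJ and petN. psbD, which encodes the D2 protein of photosystem II, had signals of 9122 ± 1788 and 4641 ± 956 (log2 fold change -0.98, SE 0.18). petG, a cytochrome b6f subunit, had 1228 ± 60.5 and 689.8 ± 108 (-0.83, SE 0.15), and ndhG was at -0.82 (SE 0.15). The 3 pif1-2 arrays had group medians of -0.12, -0.23 and -0.42 relative to the wild-type mean, the lowest on replicate 3, and the wild-type arrays -0.095, 0.090 and 0.0067. Without wild type replicate 2 the group median was -0.15 (camera adjusted p = 1.7e-05). The 13 mitochondrion-encoded probe sets had a median of 0.052 (limma camera adjusted p = 0.848), which was -0.023 without wild type replicate 2 and -0.11 without pif1-2 replicate 3. The 26 plastid-encoded genes for gene expression and other functions had a median of -0.062 (camera adjusted p = 0.499). It was -0.13 to -0.019 without 1 array and -0.10 with quantile normalization. Among them were ycf4 at -0.51 (SE 0.12) and rps16 at -0.56 (SE 0.18). For 56 nuclear genes of plastid biogenesis and photosynthesis assembly the median was -0.10 (camera adjusted p = 0.0668), with LIL3:2 at -0.68 (SE 0.19). Of the 60 genes named in that group before the filter, 10 are on the fixed lists. That group passed without wild type replicate 2 (0.0452) or pif1-2 replicate 2 (0.0103) and with the replicate number as a block (0.0492), and its median was -0.011 without pif1-2 replicate 3.

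**Figure D3:**
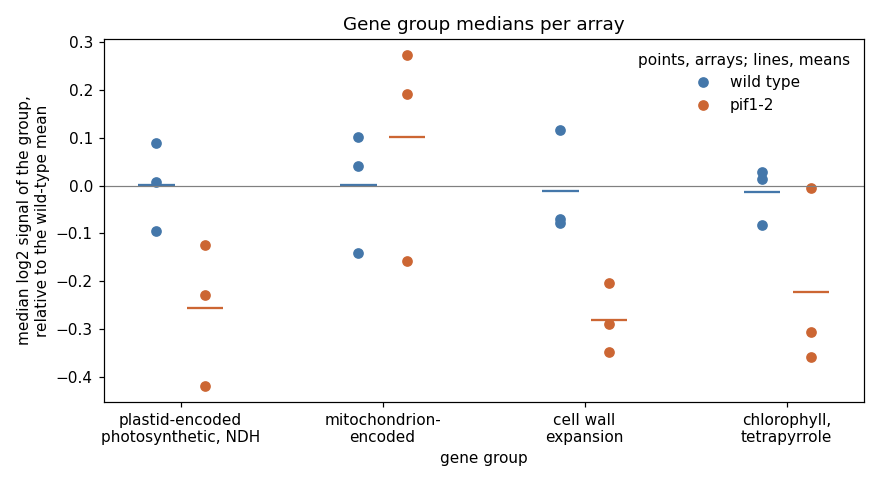
Median log2 signal of 4 gene groups on each array, relative to the mean of the wild-type arrays (vertical axis), with points for arrays and lines for group means. The pif1-2 arrays lie below the wild-type arrays for the plastid-encoded group (-0.12, -0.23 and -0.42) and the cell wall list, and the groups overlap for the mitochondrion-encoded genes and for the chlorophyll list.

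Storage lipid mobilisation was represented by SDP1, the triacylglycerol lipase of seed oil breakdown, and ICL, the isocitrate lyase of the glyoxylate cycle. SDP1 was measured at 856 ± 110 in wild type and 1120 ± 18.6 in pif1-2 (log2 fold change 0.39, SE 0.14), ICL at 9144 ± 3084 and 11809 ± 661 (0.42, SE 0.19, but 0.68 without wild type replicate 1 and 0.22 without wild type replicate 3). Neither passed over all genes, SDP1 was higher when adjusted over the list alone, and the pair missed the threshold as a list (camera adjusted p = 0.0792). The list passed without wild type replicate 1 (0.0203) and with array weights (0.0400).

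The remaining lists did not pass the threshold (camera adjusted p from 0.476 to 0.644), and none of their members passed with limma over all genes, adjusted over the list alone, or at an unadjusted p under 0.05. Few of their fixed genes were tested: 4 of 28 for auxin, 3 of 23 for gibberellin, 1 of 14 for ethylene and 1 of 15 for the clock. For photoreceptors it was 1 of 25, for PIF-related factors 2 of 12, for root markers 3 of 15 and for reference genes 3 of 9. These tests therefore say little about the pathways as wholes. Among the 4 auxin genes tested, GH3.3 and WES1, which conjugate auxin to amino acids, had log2 fold changes of 0.25 (SE 0.14) and 0.19 (SE 0.14). The gibberellin receptors GID1C, GID1B and GID1A were at 0.20, 0.029 and -0.0023, EIN3, a transcription factor of the ethylene response, at 0.19, and GI, a component of the circadian clock, at -0.19. FHL, which helps to bring phytochrome A into the nucleus, was at -0.31 (SE 0.20, from -0.51 without pif1-2 replicate 2 to -0.099 without pif1-2 replicate 3), and the basic helix-loop-helix factors ALC and SPT were at -0.40 (SE 0.31) and -0.14 (SE 0.16), with -0.62 and -0.24 without pif1-2 replicate 2, and -0.14 and 0.015 without pif1-2 replicate 3. The root markers AT1G30870, EXPA18 and EXPA7 were at -0.42 (SE 0.31), -0.22 (SE 0.25) and 0.17 (SE 0.41), and the reference genes AT2G28390 and AT4G34270 at -0.12 and -0.060. The lists of heme and bilin genes, light-exposure genes, brassinosteroid genes, and abscisic acid and dormancy regulators had 0 named probe sets, and those of seed storage and of singlet oxygen, touch and defence genes had 0 past the filter, so that these 6 were not analysed here.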

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

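The comparison of control probe sets in this part was chosen after the data were seen, and no explanation was tested for it. Of 58 Affymetrix control probe sets with a mean signal of at least 50, which the comparison of seedling genes did not use, 4 were higher on all 3 pif1-2 arrays than on all 3 wild-type arrays and 3 were lower on all; chance gives 5% in each direction, which is 2.90 of 58. The middle probe set of the actin control (Athal-Actin_M_at) had a ratio of mean signals, pif1-2 over wild type, of 1.14, with 3718 ± 305 against 3248 ± 200 (SD, n = 3). The 3-prime probe set of a ubiquitin control (r2-At-Ubq-3_x_at) had a ratio of 1.07. The 5-prime probe sets for the bacterial transcripts bioB (r2-Ec-bioB-5_at) and bioD (r2-Ec-bioD-5_at), which are added at hybridisation and owe nothing to the seedlings, had ratios of 1.3 and 1.25. Another such transcript, bioC, ran the other way on its 5-prime probe sets, with ratios of 0.757 and 0.711, as did a 5-prime probe set of GAPDH, at 0.823.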

How the results depend on the processing

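No test of this part was chosen after its result was seen, apart from running the settings on the 18 added groups and their members, on 265584_at, PPDK and AT4G33150, and counting moves of over 1.5 times. The checks of PIF1 and AT2G20810 under each setting were not run, as neither locus had a named probe set; MAS5 signals near background limit what dim probe sets can show. Over the settings, 265584_at passed in 17 of 18 (adjusted p from 2.5e-04 to 0.0615) and AT5G57760 in 8 of 18 (0.00469 to 0.271); over 71 named genes 20 calls were gained, 5 of them outside the block, 11 were lost, and 12 signs of uncalled genes turned; over 30 lists and groups 6 calls were gained, 23 lost and 28 uncalled directions turned. The plastid-encoded group passed in 18 of 20 settings, the cell wall list in 11 of 20 and the chlorophyll list in 8 of 20. These counts include settings that could hardly differ from the main fit. The fit without a trend and the robust fit do not enter camera, so the lists there repeat the main result by construction. Signals as deposited differ from the main scaling by nearly the same factor on every array (1.012 to 1.013). Why calls were gained or lost was not tested.

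The count of calls was 1, lower, with quantile normalization, median centring, no filter or no trend, and 8, all lower, with array weights. With an estimated correlation or with fry 0 fixed lists passed, and the medians stayed by construction at -0.23 (chlorophyll; adjusted p = 0.619 and 0.382), -0.32 (cell wall; 0.565 and 0.218) and -0.23 (plastid-encoded; 0.901 and 0.381). Fixed lists past the threshold numbered 1 with a pseudocount of 64 (chlorophyll -0.20), 0 with median centring (chlorophyll -0.20, cell wall -0.29), 0 with no filter or a filter at 100 (-0.22 and -0.32 in both) and 3 with array weights. Without 1 array the calls ranged from 0 to 7 (0 to 1 higher, 0 to 6 lower), the lists past the threshold from 0 to 2, the chlorophyll median from -0.30 to -0.18 and the cell wall median from -0.36 to -0.18.

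Whether the replicate numbers pair the arrays stays open, as the labels do not say. The deviations of same-numbered arrays correlated at 0.251, 0.0988 and 0.0880, 1 of 3 over the limit of 0.1. All 3 were positive, and 6 of 6 arrays correlated best with their own number. The replicate 1 arrays of the groups lay together on the second principal component and had the highest correlation of log2 signals of all pairs (0.974). The main fit did not treat the arrays as pairs. With the number as a replicate block 45 probe sets passed (11 higher, 34 lower) and 0 fixed lists (chlorophyll -0.23, adjusted p = 0.0690; cell wall -0.32, 0.0553). Of the named genes 15 were gained with it, among them EXPA9, petG, ndhG, psbD, PPDK and WAG2, and of the other breakdown genes MCCB passed.

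Directions that turned were all of uncalled results, some in camera with the median's sign kept. They were SCPL (-1.4e-04 with a pseudocount of 64, -0.0046 with quantile normalization, 0.0038 with a filter at 100, -0.023 with array weights), cold and dehydration (0.033 with fry and with no filter, 0.016 with quantile normalization), TET (0.016 with quantile normalization), CYP (0.022) and TBL (0.024) with no filter, LHCB4.3 (0.094) with array weights, and the ubiquitin ratio difference (-0.661 for 3-prime to middle). The median alone changed sign for auxin genes (-0.026 with no filter, -0.052 with a filter at 100), TET (-0.010 with a filter at 100), GST (0.0038) and wall enzymes (0.0070) with median centring, both with no filter (0.058, 0.010), and light-harvesting genes (-0.012 with quantile normalization). Without 1 array the ranges were -0.18 to 0.14 for LHCB4.3, -0.23 to 0.045 for AT2G28390, -0.21 to 0.22 for AT4G34270, -0.093 to 0.17 for GID1B, -0.023 to 0.28 for LHCB4.2, -0.24 to 0.015 for SPT, and, as list medians, the wider auxin group -0.13 to 0.14, SWEET -0.24 to 0.065, gibberellin -0.054 to 0.17, CYP -0.029 to 0.11, light-harvesting -0.023 to 0.24, TBL wall acetylation family 0.0036 to 0.11, UDP-glycosyltransferases -0.082 to -0.011, cold and dehydration -0.11 to 0.14, glutathione transferases -0.27 to 0.16, mitochondrion-encoded -0.11 to 0.23, reference genes -0.19 to 0.0035, root hair and root endodermis markers -0.49 to -0.071, serine carboxypeptidase-like -0.069 to 0.0092 and tetraspanins -0.090 to 0.13. In all, 31 of 71 named genes and 27 of 30 lists and groups moved by over 1.5 times or changed sign without 1 array, also LIL3:2 (-0.42 at the weakest), PSAN (0.24), LYC (-0.089), Z-ISO (-0.054), LHCB4.1 (0.014), EIN3 (0.090), GI (-0.089), GID1C (0.086), WES1 (0.11), AT1G30870 (-0.20) and EXPA18 (-0.071).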

Other observations

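Of the tests in this part, those of root markers, of CYP genes in either direction and of other splits for the amino acid breakdown genes and the unadjusted count were chosen after the result was seen, as were the bootstrap intervals for leaving out an array and the demand that the mitochondrial bound hold without each array, and the gene groups were defined after the annotation had been seen. With all 6 arrays none of the other added groups passed in pif1-2 against wild type (camera adjusted p from 0.0668 to 0.971 over the 17 groups not called, those of the report included). The autophagy genes ATG8 and ATG3 had a median log2 fold change of 0.11 with 8 of 10 positive (camera adjusted p = 0.247), led by ATG8B at 0.39 (SE 0.14) and ATG3 at 0.34 (SE 0.14). Among 20 auxin genes, 4 of them also on the fixed list, the median was 0.039 (adjusted p = 0.645) over members that went both ways: adjusted over the group alone, IAA34 was higher, with signals of 164 ± 24.1 in wild type and 318 ± 32.1 in pif1-2 (0.90, SE 0.18), and WAG2, a protein kinase, lower, with 954 ± 104 and 547 ± 146 (-0.82, SE 0.20). Over all genes neither passed with limma.

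The enzyme families included 32 UGT genes (median log2 fold change -0.042, UGT85A4 at -0.50 and UGT84A4 at -0.42), 15 CYP genes (0.022, CYP71B22 at 0.99 and CYP71B38 at 0.78), 13 beta-glucosidases (0.098, BGLU41 at 0.74 and BGLU45 at 0.73) and 10 glutathione transferases (-0.018, and 0.0038 with median centring, GSTL3 at -0.35 and GSTU16 at 0.35). The CYP genes went both ways, with CYP71B27 at -0.86 (SE 0.40), and a fry test of change in either direction gave an unadjusted p of 5.0e-06. It was the smallest such fry p of all lists and groups, before the cell wall list (4.7e-04) and the plastid-encoded photosynthetic group (0.0032). Only 2 CYP genes had an unadjusted limma p under 0.05, CYP71B22 and CYP71B38, both dim, with wild-type means of 34.0 and 67.3. The beta-glucosidase median was 0.023 to 0.20 without 1 array, and the group passed without pif1-2 replicate 2 (median 0.20, camera adjusted p = 0.0380). The 12 SWEET transporters had a median of -0.10, with SWEET3 at -0.53 and SWEET17 at -0.31, and the 13 tetraspanins 0.023, with TET2 at -0.36 and TET8 at 0.25. The 17 genes of the cold and dehydration group had a median of 0.033, with COR27 at 0.60. OLEO3, an oleosin that the symbol pattern took into this group, was lower when adjusted over the group alone. For 19 SCPL genes (scpl33 at -1.15, SCPL45 at -0.28) the median was 0.0038 (-0.0046 with quantile normalization) and the mean -0.033, and for 17 TBL genes (TBL37 at 0.38, TBL30 at -0.42) the median was 0.068 and the mean -0.0036, opposite in sign within each family. Without pif1-2 replicate 3 scpl33, whose pif1-2 signals were 72.5, 78.1 and 5.27, was at -0.45, SCPL45 at -0.17, SWEET3 at -0.27, TBL30 at -0.091 and GSTU16 at 0.23, and without pif1-2 replicate 2 SWEET17 was at -0.18 and UGT84A4 at -0.23. Of the mitochondrion-encoded genes, ccb452 was at -0.72 (SE 0.22) and ccb382 at 0.26 (SE 0.13).

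A hypothesis of higher amino acid breakdown in dark-grown pif1-2 came from genes picked out for their values: PPDK, pyruvate orthophosphate dikinase, at a log2 fold change of 0.90 (SE 0.19, limma adjusted p = 0.251), AT4G33150, the bifunctional enzyme of lysine breakdown, at 0.75 (SE 0.16, 0.251), and ICL, at 0.42 (0.22 to 0.68 without 1 array). A list of 10 other genes of amino acid breakdown, written before their values were read, was then tested. All 10 were positive, with a median of 0.45 (95% bootstrap interval over genes 0.25 to 0.53). The unadjusted camera p was 3.6e-07, and 0.0460 with an estimated correlation. The estimated-correlation values given above for the other lists are adjusted. Unadjusted, these camera p-values were 0.0513 for the cell wall list, 0.169 for the chlorophyll list and 0.105 for the plastid-encoded group. The list of 10 was not run under the alternative settings or without each array. Its members included MCCB and MCCA, the subunits of methylcrotonyl-CoA carboxylase in leucine breakdown, at 0.84 (SE 0.22) and 0.58 (SE 0.14), IVD at 0.45 and the electron transfer protein ETFQO at 0.31. With limma 0 of the 10 passed over all genes (6 at an unadjusted p under 0.05), and MCCB passed with the replicate number as a block (adjusted p = 0.0394). The list medians of the pif1-2 arrays, relative to the wild-type mean, were 0.37, 0.37 and 0.47, and those of the wild-type arrays 0.27, -0.096 and -0.16. A wider shift of breakdown genes may be present, as a hypothesis found and tested on the same arrays; its cause was not tested. Across the 10 splits of the 6 arrays, 1 (the real one) gave so small a camera p, and the smallest of the other splits was 4.0e-05. With 10 splits no share under 0.05 can be had.

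The lower plastid-encoded transcripts were set against 3 technical explanations. A shift shared by probe sets of similar brightness is argued against, as 0 of 10000 random lists matched on mean signal had so low a median. Their central 95% lay between -0.031 and 0.12. Without the array of pif1-2 replicate 3 the median was still negative, at -0.18 against -0.23 with it. The 95% bootstrap interval over genes, -0.27 to -5.0e-04, treats the genes as independent. With an estimated correlation of 0.25 between them it is too narrow to decide, and the part of that array stays open. Without wild type replicate 2 the median was -0.15. Less capture of RNA without a poly(A) tail in pif1-2 stays open. The mitochondrion-encoded median was 0.052 (-0.10 to 0.31), above a bound set beforehand midway between 0 and the plastid-encoded median. That bound was not met without pif1-2 replicate 3, where the medians were -0.11 for mitochondrion-encoded and -0.18 for plastid-encoded genes. Without any 1 of the other arrays the mitochondrion-encoded median was -0.023 to 0.23. On pif1-2 replicates 1, 2 and 3, relative to the wild-type mean, mitochondrion-encoded medians were 0.19, -0.16 and 0.27. The plastid-encoded medians there were -0.12, -0.23 and -0.42. The 25S rRNA signal, of 1 probe set, ran from 545.5 to 13935.5 within pif1-2. The call needs the preset correlation, and 1 of the 10 splits of the arrays (the real one) gave so small a camera p, 3.3e-09, with 1.7e-05 the smallest of the others, where 10 splits are too few for a share under 0.05. A lower plastid content or transcription in pif1-2 may also be behind it, as a hypothesis that was not tested. The 26 plastid-encoded genes for gene expression and other functions had a median of -0.062, with 15 negative and 11 positive (camera adjusted p = 0.499).

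For the lower cell wall expansion list, 0 of 10000 random lists matched on mean signal had so low a median, which argues against a shift shared by probe sets of that brightness. Without the array of pif1-2 replicate 3 the list median was -0.32 as before (95% bootstrap interval -0.80 to 0.01), but over 8 genes the interval reaches past 0 and the camera adjusted p was 0.143, so the part of that array stays open. A smaller share of root tissue in the shorter pif1-2 seedlings could not be separated: the root markers had a median of -0.22, but with 3 genes from -0.42 to 0.17, in seedlings that were harvested whole, they do not decide. The difference in height named by the labels may also go with wall enzymes, and was not tested. Of the 10 splits, 1 (the real one) had so small a camera p, 0.0052, the smallest of the others being 0.0659.

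For the other results that compare the groups, the 10 splits of the 6 arrays allow no share under 0.05. The real split gave 2 calls and the highest of the others 0, with 1 split reaching as many. For probe sets at an unadjusted p under 0.05 the real split gave 1357 and the highest of the others 1666, with 3 of the 10 splits reaching as many. For the chlorophyll and tetrapyrrole list 1 split, the real one, had so small a camera p (0.0071), the smallest of the others being 0.00938.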
